A study of Mus musculus with 12 samples.

How the data were processed

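The series holds bulk mRNA sequencing of ear skin from C57BL/6 mice aged 8 to 12 weeks, in 12 libraries that fall into 4 groups of 3. All titles name day 6. IMQ_Veh, IMQ_GW3965 and IMQ_Troglitazone are the groups whose labels name imiquimod, an activator of Toll-like receptor 7 that is used to provoke psoriasis-like inflammation in mouse skin. Per the labels, it was given daily as 20.8 mg of Aldara cream (5% imiquimod by weight) on the back of the ears, and tissue was taken 1 day after the last dose. GW3965, an agonist of the liver X receptors (LXR), was injected into the peritoneum at 20 mg/kg, and troglitazone, an agonist of the peroxisome proliferator-activated receptor PPARγ, at 150 mg/kg, each once per day from day 3. DMSO was the vehicle. The group UTX_Veh carries no imiquimod in its label; the labels do not spell out UTX. The labels do not say that the 3 libraries of a group come from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. The doses of the drugs differ and the compounds are not structural analogs.

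Per the labels, RNA was isolated with a mirVana kit, treated with DNase and made into libraries with a TruSeq stranded mRNA kit. The submitters' processing notes name FastQC, Trim Galore, STAR 2.7.3a, RSEM 1.3.3 and the mouse build GRCm38 (mm10). The annotation release, the strand setting of RSEM and all other settings are not given in the sources used here. The authors deposited 1 RSEM gene table per library, and the values used here are its expected counts, which are estimates of the reads of each gene, not scaled for depth and not always whole. RSEM divides reads that fit several genes among them, so values of near-identical family members (the Sprr2, Lce, Scd, Krt6, Hba, Hbb and Defb genes) depend on that division, and antisense partners could be mixed because the strand setting is not given.

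Each table held 55416 Ensembl gene identifiers. Symbols and coordinates were taken from GENCODE M21 (GRCm38), which matched 52083 identifiers; 3333 had no match and were kept under their identifier, so the authors' annotation release differs from the one used for names. Printed positions are those of GENCODE M21 genes on GRCm38. Total expected counts per library ranged from 18242074 to 25641602. No pair of libraries of a group agreed within sampling noise, as copies of a single library would: the lowest chi-square per degree of freedom was 8.34, between UTX_Veh replicates 1 and 3.

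Expected counts were rounded to whole numbers and analysed in R 4.3.3. Genes passing the filterByExpr rule of edgeR 4.0.16 by group were tested (17130 genes), with TMM scaling and edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in a single fit of all 12 libraries with 8 residual degrees of freedom. The common dispersion was 0.0306. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05, with no fold limit. CPM are counts scaled to a common library size by TMM and are given as mean ± SD over the 3 libraries of a group. Where a group had 0 counts in all 3 libraries, a lower bound on the fold was computed from unscaled CPM, against a floor of 3 counts over the group; where it had 1 to 3 counts, CPM are given without a fold. A list's median was also computed with members at 0 set to that bound. Genes below the filter are given as unscaled CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

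Before the data were examined, the groups, the tests, the alternatives, 28 gene lists (671 symbols, 669 matched, 599 list genes tested) and the rule for naming genes were fixed. The rule took, per main comparison, the 8 changed genes with the largest fold in each direction, with a mean of at least 1 CPM and no overlap of the groups. It also took up to 4 changed members of each list (or the 2 most abundant where none changed) and 20 fixed genes. Predicted or unnamed gene models were counted and not named: 676 for IMQ_Veh against UTX_Veh, 67 for GW3965 and 94 for troglitazone against IMQ_Veh, and 21 between the drugs. For each list the members past the threshold over all genes and adjusted over the list alone were counted. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data, and with fry, each adjusted over the 28 lists of a comparison.

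The alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a fit of only the 2 groups compared, the replicate number as a block, the lane field in the file names (L001 or L009, which the labels do not explain) as a covariate, both together, leaving out each library in turn, and removing hemoglobin, muscle and mitochondrial genes. Added after the data were seen were fits without IMQ_Veh replicate 3 and IMQ_GW3965 replicate 3 together, fits without the feature ENSMUSG00000119584 and Lars2, and corrections of each library for transcript length (the length column of the deposited tables, mean over libraries) or for transcript GC content (99.8% of tested genes), each by a lowess curve with a span of 0.3. Lists were scored per library as the mean log2 CPM of their members, with a pseudo count of 2. Comparisons that share control libraries were set against 40 simulations of unchanged groups.

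The steps were tested on simulated data after the first fit of the real counts. With counts simulated for GW3965 against IMQ_Veh over 16919 genes, the test found 9 of 67 genes changed 1.5-fold, 40 of 67 changed 2-fold and 59 of 66 changed 4-fold, and 3 of its 111 calls were false. With a length trend and no other change simulated between the drug groups, 491 genes were called before the length correction and 0 after it by edgeR; of 100 genes changed 2-fold besides the trend, 50 were called after it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.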

Results

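Bulk mRNA was measured in the ear skin of C57BL/6 mice on day 6, in 12 libraries from 4 groups of 3. UTX_Veh had no imiquimod in its label, IMQ_Veh had imiquimod with the DMSO vehicle, and IMQ_GW3965 and IMQ_Troglitazone had imiquimod with an agonist of LXR or of PPARγ, nuclear receptors that switch on genes of lipid transport and synthesis. Total expected counts lay between 18242074 in IMQ_GW3965 replicate 3 and 25641602 in IMQ_Veh replicate 2. Among the libraries, 2 stood apart in the makeup of their counts. IMQ_GW3965 replicate 3 had 11.62% of its counts in the feature ENSMUSG00000119584, which held 0.045% to 0.138% elsewhere. In IMQ_Veh replicate 3, skeletal muscle genes made up 0.901% of counts, against 0.226% and 0.265% in the other IMQ_Veh libraries. The labels do not state that replicates were separate animals, so p-values measure only the spread between these samples. Comparisons, gene lists and the rule for naming genes were chosen before the data were examined. Values are CPM, mean ± SD with n = 3, and log2 fold changes are given ± SE.

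IMQ_Veh was compared with UTX_Veh, whose label names no cream, so imiquimod and cream base were not separated. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035 on GRCm38) and S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), which encode the subunits of the antimicrobial protein calprotectin, rose from 3.40 ± 2.57 to 2940 ± 890 CPM (log2 9.74 ± 1.04, edgeR adjusted p = 1.56e-05) and from 4.99 ± 5.09 to 5420 ± 1480 CPM (log2 10.07 ± 1.17, edgeR adjusted p = 2.69e-05). The wound keratins Krt6a (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307) and Krt16 rose from 49.2 ± 16.3 to 7710 ± 1360 CPM and from 18.8 ± 17.0 to 8580 ± 1820 CPM (log2 7.29 ± 0.46 and 8.83 ± 0.76, edgeR adjusted p = 7.22e-07 and 3.81e-06). Il17a, the cytokine that drives keratinocytes in psoriasis, had 0 counts in UTX_Veh and 1.90 ± 1.43 CPM in IMQ_Veh, at least 37.9-fold higher (edgeR adjusted p = 0.000889; at least 22.2-fold without IMQ_Veh replicate 2 and 24.8-fold without UTX_Veh replicate 1), and Il17f and Il23a rose by log2 6.23 ± 1.29 and 3.44 ± 0.67. Without UTX_Veh replicate 1, S100a8, S100a9, Krt16, Il17f and Il23a were at log2 10.51, 11.35, 9.86, 7.49 and 4.48, and Il17f was at 5.51 without IMQ_Veh replicate 2. Flg2 (ENSMUSG00000049133, chromosome 3, 93197278 to 93221391), which encodes a filaggrin-like protein of the skin barrier, fell from 1550 ± 93.7 to 77.6 ± 41.7 CPM (log2 -4.32 ± 0.40, edgeR adjusted p = 6.16e-06).

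Of 17130 genes tested, 10595 changed, 5644 higher and 4951 lower. Upper-quartile scaling, under which the median log2 of all genes was -0.114 instead of 0.007, gave 4805 higher and 5870 lower. Among the genes with names and at least 1 CPM, those with the largest increases included Sprr2b (log2 12.24 ± 1.17), Stfa1 (10.29 ± 0.81) and Saa3 (9.84 ± 1.17), together with Defb3, which had 0 counts in UTX_Veh and 23.6 ± 8.78 CPM in IMQ_Veh, at least 468-fold higher (306-fold without UTX_Veh replicate 1). Defb4 had 0.0131 ± 0.0227 CPM in UTX_Veh and 19.3 ± 8.80 CPM in IMQ_Veh. The largest decreases included those of Tgm7 (log2 -5.61 ± 0.61), Mrgprb3 (-5.37 ± 0.58), Krtap3-2 (-5.10 ± 0.53), Paqr7 (-4.95 ± 0.33) and Krt77 (-4.60 ± 0.77). Stfa1 and Saa3 were at log2 12.34 and 10.92 without UTX_Veh replicate 1 and Sprr2b at 13.38 without UTX_Veh replicate 3. Saa3, Krtap3-2 and Krt77 were at 9.22, -5.83 and -6.47 without IMQ_Veh replicate 3, and Tgm7 at -6.19 without IMQ_Veh replicate 2. Values of the Sprr2, Lce, Krt6, Defb, Scd and hemoglobin families are uncertain, because RSEM could split reads among near-identical copies.

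Several inflammatory and epidermal lists moved upward with IMQ_Veh. Of 28 tested genes of the IL-23/IL-17 axis and IL-36 cytokines, 26 were higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 7.43e-08, adjusted p = 0.355 with an estimated correlation). Csf3 was at least 55.5-fold higher (at least 23.2-fold without IMQ_Veh replicate 3 and 36.4-fold without UTX_Veh replicate 1), and Cxcl5 and Cxcl3 went from 0.0139 ± 0.0241 and 0.0262 ± 0.0454 to 13.5 ± 7.29 and 14.0 ± 4.24 CPM. Of 15 antimicrobial genes, 14 were higher and 1 lower by either adjustment, also adjusted over the list alone (camera adjusted p = 6.85e-09, adjusted p = 0.159 with an estimated correlation). All 29 genes of wound keratins and cornified envelope precursors were higher, likewise adjusted over the list alone (camera adjusted p = 2.51e-29, adjusted p = 0.159 with an estimated correlation). Members included Lce3b and Krt6b at log2 9.69 ± 0.94 and 9.57 ± 1.31, and at 11.39 and 12.14 without UTX_Veh replicate 1. All 30 cell cycle genes were higher, likewise adjusted over the list alone (camera adjusted p = 4.1e-32, adjusted p = 0.159 with an estimated correlation). They were led by Plk1 and Aurka at log2 3.46 ± 0.21 and 3.18 ± 0.24. Suprabasal differentiation genes went both ways, with 16 of 29 higher and 5 lower, the same counts adjusted over the list alone (camera adjusted p = 0.121, and 0.000754 without IMQ_Veh replicate 2). Rptn and Krt1 rose by log2 6.93 ± 0.56 and 4.32 ± 0.34. For the suprabasal list the camera adjusted p ranged from 0.000754 to 0.322 over the alternative fits.

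Among immune cell lists, 15 of 17 neutrophil markers were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 1.48e-09, adjusted p = 0.159 with an estimated correlation). Fpr1 was at least 67.0-fold higher and Trem1 at log2 7.20 ± 0.61 (at least 43.9-fold and log2 7.82 without UTX_Veh replicate 1). Of 26 monocyte and macrophage markers, 18 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00671, adjusted p = 0.747 with an estimated correlation), and it was not called without IMQ_Veh replicate 3 (0.063). Cd14 and Fcgr1 rose by log2 3.20 ± 0.26 and 2.97 ± 0.44. Among 26 T cell and innate-like lymphocyte markers, 3 were higher and 13 lower, the same adjusted over the list alone (camera adjusted p = 0.075, and 0.0432 without UTX_Veh replicate 2). Cd3e and Tcrg-C4 fell by 1.69 ± 0.20 and 1.57 ± 0.42 on the log2 scale. Among 30 interferon-stimulated genes, 6 were higher and 0 lower by edgeR, with 1 higher adjusted over the list alone (camera adjusted p = 0.944, direction down although the median was 0.26). Oas1a and Oas2 were among the 6, at log2 2.05 ± 0.58 and 1.40 ± 0.43. Without IMQ_Veh replicate 3, whose interferon score stood above those of the other IMQ_Veh libraries, they were at 1.14 and 0.64, and Oas2 was no longer past the threshold. Over the alternative fits camera adjusted p ranged from 7.46e-07 to 0.063 for monocytes and from 0.0161 to 0.225 for T cells.

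Type 2 immunity, named in the title of the series, was read from several lists. Il4 and Il13 were too low to test, at 0.0390 ± 0.0675 and 0.381 ± 0.110 CPM in IMQ_Veh and 0.0627 ± 0.0702 and 0.129 ± 0.0599 CPM in UTX_Veh. Il4ra, the receptor subunit they share, rose from 35.2 ± 5.22 to 141 ± 26.3 CPM (log2 2.01 ± 0.30, edgeR adjusted p = 0.000159). Of 19 type 2 cytokine, receptor and chemokine genes, 9 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.516). Areg rose by log2 5.00 ± 0.47, and Il17rb fell by 1.53 ± 0.27. Among 19 genes of alternatively activated macrophages, 5 were higher and 7 lower, the same adjusted over the list alone (camera adjusted p = 0.534, direction down, median -0.34, mean 0.10). Chil3 and Arg1 rose by log2 5.44 ± 0.76 and 4.48 ± 0.61, and Retnla fell by 4.30 ± 0.81 (log2 -3.68 and -5.35 without IMQ_Veh replicates 2 and 3). Of 6 eosinophil and basophil markers, 1 was higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.866, direction down, median -0.29, mean 0.45). Ear1 went from 0.0142 ± 0.0247 to 0.574 ± 0.0869 CPM. Of 15 mast cell markers, 2 were higher and 4 lower, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.905). Hdc, which is also in the neutrophil list, rose by log2 3.16 ± 0.21, and Mrgprb2 and Kit fell by 1.80 ± 0.42 and 1.01 ± 0.23. Among 22 dendritic and Langerhans cell markers, 4 were higher and 8 lower, the same adjusted over the list alone (camera adjusted p = 0.436). Cd80 rose by log2 1.86 ± 0.22, and Mgl2 and Cd207 fell by 1.57 ± 0.27 and 1.07 ± 0.14. Of 4 B cell and plasma cell markers, 3 were higher, the same adjusted over the list alone, with Cd79b and Blnk among them at log2 1.99 ± 0.44 and 0.73 ± 0.13 (camera adjusted p = 0.205).

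Lipid genes were measured because both drugs act on lipid-sensing receptors. Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581), the transcription factor of fatty acid synthesis, fell from 252 ± 12.3 to 131 ± 25.4 CPM (log2 -0.95 ± 0.14, edgeR adjusted p = 0.000181), and the desaturase Scd1 from 5460 ± 169 to 1780 ± 662 CPM (log2 -1.62 ± 0.25, edgeR adjusted p = 0.000173). The drug receptors Pparg and Nr1h2 fell by 1.09 ± 0.17 and 0.35 ± 0.08 on the log2 scale, Nr1h2 not past the threshold after a GC correction, and Nr1h3 had log2 -0.57 ± 0.31 (edgeR adjusted p = 0.128). Among receptor targets, Abca1 and Cd36 fell by 0.60 ± 0.24 and 0.76 ± 0.24, Angptl4 rose by log2 2.02 ± 0.33, and Abcg1, Fabp4 and Pdk4 had edgeR adjusted p of 0.0657, 0.367 and 0.251. Cd36 was not past the threshold without UTX_Veh replicate 3 (log2 -0.68), nor Abca1 without UTX_Veh replicates 2 or 3 or IMQ_Veh replicates 1 or 2 (-0.67, -0.44, -0.70 and -0.44) or after a length correction (-0.05). Of 27 LXR target genes, 5 were higher and 14 lower, with 6 and 14 adjusted over the list alone (camera adjusted p = 0.12). Ch25h rose by log2 2.58 ± 0.44, and Mlxipl fell by 1.66 ± 0.37. Of 45 PPAR target genes, 12 were higher and 16 lower, the same adjusted over the list alone (camera adjusted p = 0.605), with Fabp5 and Gk up by log2 4.10 ± 0.23 and 3.92 ± 0.38 and Txnip at log2 -2.16 ± 0.42. Of 26 cholesterol synthesis genes, 20 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00139, adjusted p = 0.703 with an estimated correlation). Ebp and Fdps rose by log2 1.38 ± 0.12 and 1.28 ± 0.15. Of 27 fatty acid synthesis genes, 4 were higher and 13 lower, the same adjusted over the list alone (camera adjusted p = 0.0255, adjusted p = 0.625 with an estimated correlation). They included Acacb at log2 -2.05 ± 0.25. Of 22 sebaceous gland genes, 2 were higher and 12 lower, the same adjusted over the list alone (camera adjusted p = 0.0255, adjusted p = 0.703 with an estimated correlation), and it was not called without IMQ_Veh replicate 3 (0.174). Mc5r fell by 2.83 ± 0.26, and Defb6, also in the antimicrobial list, rose by log2 2.80 ± 0.26. For the sebaceous list the camera adjusted p ranged from 4.67e-05 to 0.249 over the alternative fits.

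Muscle, cartilage and adipocyte lists moved downward, and in IMQ_Veh replicate 3 they stood above the other IMQ_Veh libraries by 1.95, 1.43 and 1.43 on the log2 scale. All 23 skeletal muscle markers were lower, likewise adjusted over the list alone (camera adjusted p = 5.44e-07, adjusted p = 0.696 with an estimated correlation). Members included Pvalb, Actn3 and Atp2a1 at log2 -3.58 ± 0.49, -3.34 ± 0.47 and -2.60 ± 0.47, and at -4.61, -4.33 and -3.56 without IMQ_Veh replicate 3. Of 18 cartilage markers, 17 were lower, and 18 adjusted over the list alone (camera adjusted p = 7.1e-06, adjusted p = 0.625 with an estimated correlation). They were led by Chad and Ucma at log2 -2.68 ± 0.43 and -2.23 ± 0.54, and at -3.43 and -3.55 without that library. Of 18 adipocyte markers, 8 were lower, the same adjusted over the list alone (camera adjusted p = 0.00795, adjusted p = 0.747 with an estimated correlation). Members included Lep, Car3 and Sult1a1 at log2 -2.25 ± 0.47, -1.73 ± 0.37 and -1.72 ± 0.45, with Lep and Car3 at -2.90 and -2.42 without it. Of 21 fibroblast and collagen genes, 5 were lower, with 3 adjusted over the list alone (camera adjusted p = 0.19, and 0.000835 without IMQ_Veh replicate 3). Among them were Eln and Fap at log2 -1.20 ± 0.36 and -1.14 ± 0.32, and at -1.88 and -1.75 without it. Of 19 endothelial markers, 3 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.432), with Prox1 and Cldn5 at log2 -1.64 ± 0.33 and -1.41 ± 0.32. Of 11 hair follicle keratin genes, 3 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.929, direction up, median -0.47, mean 0.08). Krt84 rose by log2 3.24 ± 0.36, and Msx2 fell by 1.25 ± 0.29. Of 20 immediate early and heat shock genes, 7 were higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.516), with Ier3 and Junb at log2 2.42 ± 0.17 and 1.63 ± 0.15. Of 7 erythrocyte genes, 5 were higher, the same adjusted over the list alone (camera adjusted p = 0.159, and 0.000496 without IMQ_Veh replicate 2), with Hbb-bt and Hbb-bs at log2 2.16 ± 0.34 and 1.68 ± 0.30. Over the alternative fits camera adjusted p ranged from 0.000835 to 0.612 for fibroblast and from 0.000496 to 0.366 for erythrocyte genes.

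**Figure D1:**
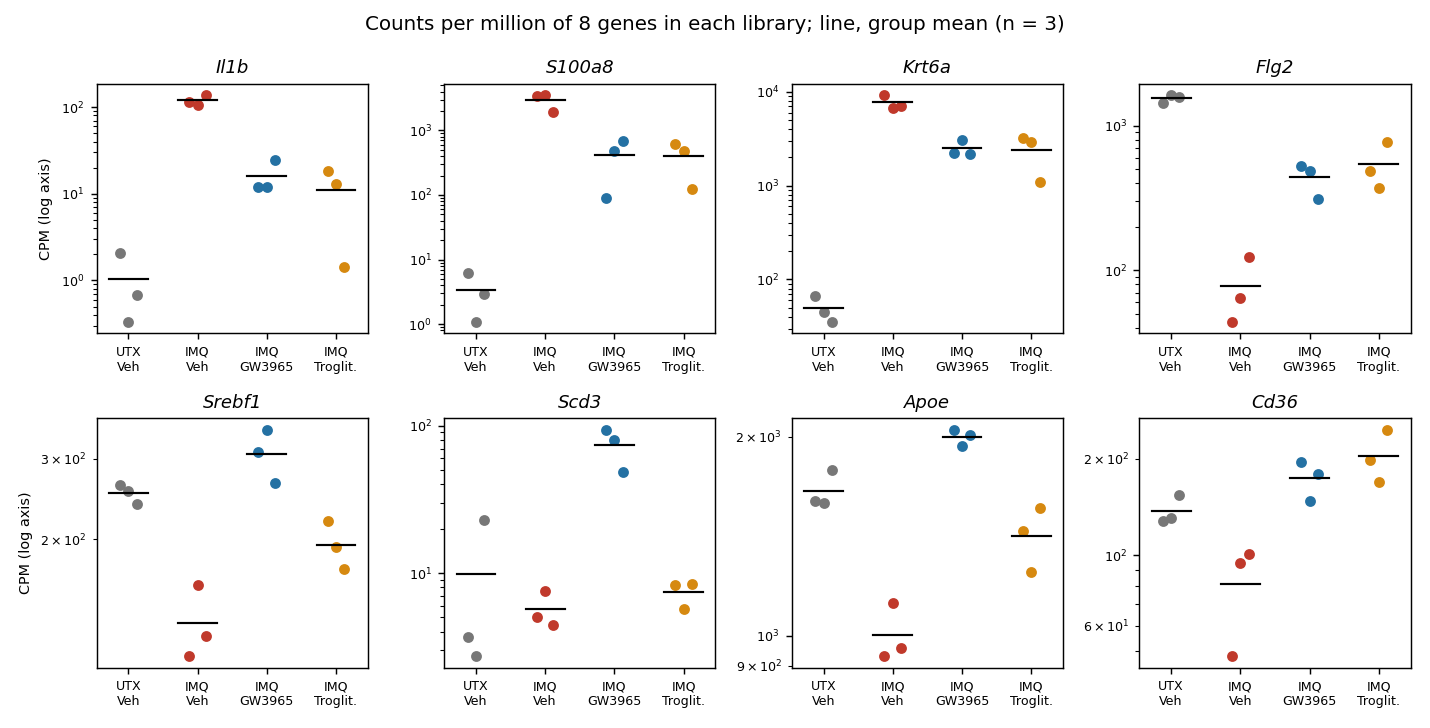
CPM (log axis) of 8 genes in each of the 12 libraries, with points for libraries and lines for group means (n = 3). Il1b, S100a8 and Krt6a had lower means in both drug groups than in IMQ_Veh, while Flg2, Srebf1 and Cd36 had higher means.

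The comparison of IMQ_GW3965 with IMQ_Veh asked what the LXR agonist changed in challenged skin. The known LXR targets Srebf1 and Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), which encodes a cholesterol carrier, rose from 131 ± 25.4 to 308 ± 41.4 CPM (log2 1.23 ± 0.15, edgeR adjusted p = 0.00277) and from 1000 ± 104 to 2000 ± 52.7 CPM (1.99-fold, edgeR adjusted p = 0.00253). The desaturases Scd3 (ENSMUSG00000025202, chromosome 19, 44203269 to 44244016) and Scd1 rose from 5.67 ± 1.63 to 74.3 ± 23.3 CPM (log2 3.70 ± 0.66, edgeR adjusted p = 0.015) and from 1780 ± 662 to 4530 ± 763 CPM (log2 1.35 ± 0.24, edgeR adjusted p = 0.0159). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), a cytokine of myeloid cells, fell from 120 ± 16.5 to 16.2 ± 7.33 CPM (log2 -2.90 ± 0.65, edgeR adjusted p = 0.0273), and Krt6a from 7710 ± 1360 to 2510 ± 505 CPM (log2 -1.62 ± 0.36, edgeR adjusted p = 0.0264). Flg2 rose to 440 ± 114 CPM (log2 2.50 ± 0.37, edgeR adjusted p = 0.00657). Abca1 and Abcg1, cholesterol exporters and LXR targets, had log2 0.78 ± 0.24 and 0.49 ± 0.18 without passing the threshold (edgeR adjusted p = 0.0703 and 0.107).

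Of 17130 genes, 1130 changed, 636 higher and 494 lower. The count rested on single libraries: it was 154, 740 and 3644 without IMQ_Veh replicates 1, 2 and 3, and 105, 385 and 412 without IMQ_GW3965 replicates 1, 2 and 3. Of 67 named genes past the threshold, 14 passed it in all 13 other fits run for named genes, among them Srebf1, Apoe, Flg2, Soat1, Fmo2, Csf3r, Ccr2 and Hdc; 48 were lost without IMQ_Veh replicate 1, 23 without IMQ_Veh replicate 2, and 51, 37 and 31 without IMQ_GW3965 replicates 1, 2 and 3, 23 with the lane field as a covariate and 2 after the length correction. The largest increases after Scd3 included those of Mrgprb3 (log2 2.82 ± 0.68), Nell2 (2.75 ± 0.45), Galnt15 (2.60 ± 0.53) and Fmo2 (2.59 ± 0.40). The largest decreases included those of Cxcl5 (log2 -3.74 ± 0.82), Acod1 (-3.54 ± 0.76), Sprr2b (-2.99 ± 0.66), Slfn4 (-2.91 ± 0.41) and Cxcl3 (-2.90 ± 0.61). Cxcl5 was at log2 -5.08 without IMQ_GW3965 replicate 2, and Acod1 at -4.30 without IMQ_GW3965 replicate 3.

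Lipid lists were higher with GW3965. Of 27 LXR target genes, 9 were higher and 0 lower by edgeR, with 16 higher adjusted over the list alone (camera adjusted p = 4.88e-09, adjusted p = 0.0212 with an estimated correlation), Pnpla3 among them at log2 0.97 ± 0.24. Of 27 fatty acid synthesis genes, 12 were higher, with 20 adjusted over the list alone (camera adjusted p = 2.94e-16, adjusted p = 0.0194 with an estimated correlation). These included Fads2 at log2 1.29 ± 0.27. The LXR and fatty acid lists gave the only list calls of this comparison that held with an estimated correlation. Of 45 PPAR target genes, 7 were higher and 1 lower, with 19 and 2 adjusted over the list alone (camera adjusted p = 1.32e-07, adjusted p = 0.267 with an estimated correlation). Cd36 and Pnpla2 rose by log2 1.10 ± 0.24 and 1.01 ± 0.22, and Fabp5 fell by 0.76 ± 0.21. Of 22 sebaceous gland genes, 8 were higher, with 14 adjusted over the list alone (camera adjusted p = 1.8e-10, adjusted p = 0.166 with an estimated correlation). Among them was Soat1 at log2 1.15 ± 0.18. Of 18 adipocyte markers, Sult1a1 and Pparg were higher, at log2 1.79 ± 0.45 and 0.89 ± 0.17, with 5 adjusted over the list alone (camera adjusted p = 7.83e-07, adjusted p = 0.363 with an estimated correlation). Of 26 cholesterol synthesis genes, Insig1 was higher at log2 0.65 ± 0.11, with 3 adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.723 with an estimated correlation), and it was not called without IMQ_Veh replicate 3 (0.587). Nr1h2, Nr1h3, Fabp4, Angptl4 and Pdk4 had edgeR adjusted p between 0.107 and 0.877. For cholesterol synthesis the camera adjusted p ranged from 9.62e-06 to 0.78 over the alternative fits.

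Several inflammatory lists were lower. Of 28 genes of the IL-23/IL-17 axis, 1 was higher and 6 lower, with 1 and 17 adjusted over the list alone (camera adjusted p = 2.07e-07, adjusted p = 0.257 with an estimated correlation). Il17a fell from 1.90 ± 1.43 to 0.165 ± 0.0344 CPM (edgeR adjusted p = 0.0499), a call lost by limma-voom, with the lane field and without IMQ_Veh replicates 1 or 2 or any IMQ_GW3965 library, while Il17f and Il23a had edgeR adjusted p of 0.0982 and 0.0945. Of 15 antimicrobial genes, Defb4, S100a8 and S100a7a were lower, at log2 -2.88 ± 0.45, -2.81 ± 0.75 and -2.43 ± 0.65, with 12 adjusted over the list alone (camera adjusted p = 3.69e-07, adjusted p = 0.166 with an estimated correlation). S100a9 was at 753 ± 560 CPM (edgeR adjusted p = 0.062). Of 29 wound keratin and envelope genes, 8 were lower, with 18 adjusted over the list alone (camera adjusted p = 8.84e-12, adjusted p = 0.257 with an estimated correlation), Serpinb3c and Sprr2d among them at log2 -2.31 ± 0.56 and -1.96 ± 0.46, and Krt16 had an edgeR adjusted p of 0.16. Of 29 suprabasal genes, 14 were higher, with 17 adjusted over the list alone (camera adjusted p = 7.29e-15, adjusted p = 0.166 with an estimated correlation), led after Flg2 by Lce1m and Lce1c at log2 2.24 ± 0.32 and 1.31 ± 0.21. Of 30 cell cycle genes, 5 were lower, with 19 adjusted over the list alone (camera adjusted p = 4.76e-11, adjusted p = 0.363 with an estimated correlation). Among them were Cenpe and Rrm2 at log2 -0.77 ± 0.14 and -0.65 ± 0.16. Of 17 neutrophil markers, 1 was higher and 7 lower, with 2 and 12 adjusted over the list alone (camera adjusted p = 1.19e-08, adjusted p = 0.166 with an estimated correlation). These included Csf3r and Trem1 at log2 -2.22 ± 0.32 and -1.96 ± 0.40. Of 22 dendritic cell markers, Cd207 was higher at log2 0.70 ± 0.14 and Ciita and Cd80 lower at -1.11 ± 0.27 and -0.90 ± 0.21, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.047, adjusted p = 0.822 with an estimated correlation). Without IMQ_Veh replicate 3 and IMQ_GW3965 replicates 1 and 2, left out in turn, this camera adjusted p was 0.448, 0.0682 and 0.182. It ranged from 0.000808 to 0.448 over the alternative fits run for lists.

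Of 23 muscle markers, 5 were higher, with 19 adjusted over the list alone (camera adjusted p = 7.29e-15, adjusted p = 0.257 with an estimated correlation). Among them were Actn3 and Pvalb at log2 2.08 ± 0.45 and 1.98 ± 0.47, and at 3.07 and 3.02 without IMQ_Veh replicate 3. Muscle genes made up 1.411%, 1.027% and 0.829% of counts in the IMQ_GW3965 libraries. Other lists were not called by camera. Of 18 cartilage markers, Cytl1 and Chad were higher at log2 1.94 ± 0.38 and 1.60 ± 0.41, also adjusted over the list alone (camera adjusted p = 0.414, direction up, median -0.01, mean 0.09, and 2.73e-05 without IMQ_Veh replicate 3, with Chad at log2 2.36). Of the monocyte markers, Ccr2 and Cd14 fell by 2.10 ± 0.29 and 1.51 ± 0.24, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.711, and 0.00591 without IMQ_Veh replicate 2). Among T cell markers Il2ra fell by 1.29 ± 0.27, as it did adjusted over the list alone (camera adjusted p = 0.234, and 0.0261 without IMQ_GW3965 replicate 3). Among type 2 genes Tslp rose by log2 1.19 ± 0.23, as it did adjusted over the list alone (camera adjusted p = 0.337), and Il4ra had log2 -0.74 ± 0.29 (edgeR adjusted p = 0.137). Il4 and Il13 were at 0.112 ± 0.065 and 0.0872 ± 0.0827 CPM, too low to test. Clec7a (log2 -3.29 without IMQ_GW3965 replicate 3) and Arg1 fell by 2.58 ± 0.50 and 2.04 ± 0.54, with 3 macrophage genes of that list lower adjusted over the list alone (camera adjusted p = 0.231, direction down, median 0.04, mean -0.39, and 0.00537 without IMQ_Veh replicate 2). Ms4a2 rose by log2 0.98 ± 0.23, the 1 eosinophil and basophil marker that did, also adjusted over the list alone (camera adjusted p = 0.577). Of the mast cell markers, Ms4a2 was higher and Hdc lower at log2 -1.33 ± 0.19, also adjusted over the list alone (camera adjusted p = 0.159, and 0.00299 without IMQ_Veh replicate 3). Hspa1a rose by log2 0.57 ± 0.09, with 1 immediate early and heat shock gene higher and 2 lower adjusted over the list alone (camera adjusted p = 0.732). Over the alternative fits camera adjusted p ranged from 2.73e-05 to 0.834 for cartilage, 0.00591 to 0.861 for monocytes, 0.0261 to 0.531 for T cells, 0.00537 to 0.857 for alternatively activated macrophages and 0.00299 to 0.783 for mast cells.

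In 6 lists 0 genes passed the edgeR threshold against IMQ_Veh, over all genes or adjusted over the list alone, and limma-voom and DESeq2 were not run by list. At an unadjusted p under 0.05 there were 1 interferon-stimulated gene, 2 hair keratins, 5 fibroblast genes and 3 endothelial markers, and 0 genes of the B cell and erythrocyte lists. Camera gave adjusted p of 0.123 for interferon-stimulated genes, 0.752 for B cell markers, 0.752 for hair keratins, 0.16 for fibroblast genes, 0.159 for endothelial markers and 0.478 for erythrocyte genes. Abundant members were Ly6a (log2 -0.11 ± 0.10), Blnk and Ighm (-0.06 ± 0.13 and 0.05 ± 0.40), Tchh (-0.76 ± 0.36), Col3a1 and Dcn (-1.42 ± 0.58 and 0.56 ± 0.23), Pecam1 (0.23 ± 0.33), and Hbb-bs (0.17 ± 0.29). Camera called interferon-stimulated genes without IMQ_Veh replicates 1 (adjusted p = 0.0168) or 2 (4.96e-06) or IMQ_GW3965 replicate 3 (0.0104), fibroblast genes without IMQ_Veh replicates 1 (0.0197) or 2 (9.89e-06), and endothelial markers without IMQ_Veh replicate 3 (0.000209). Across the alternative fits run for lists these ranged from 4.96e-06 to 0.897, 9.89e-06 to 0.564 and 0.000209 to 0.539.

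The comparison of IMQ_Troglitazone with IMQ_Veh asked the same of the PPARγ agonist. Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), a fatty acid transporter and PPARγ target, rose from 81.0 ± 28.7 to 205 ± 39.7 CPM (log2 1.34 ± 0.24, edgeR adjusted p = 0.0126), and Flg2 from 77.6 ± 41.7 to 543 ± 204 CPM (log2 2.81 ± 0.37, edgeR adjusted p = 0.00632). Il1b fell from 120 ± 16.5 to 10.9 ± 8.60 CPM (log2 -3.46 ± 0.66, edgeR adjusted p = 0.0136), S100a8 from 2940 ± 890 to 403 ± 249 CPM (log2 -2.87 ± 0.75, edgeR adjusted p = 0.0381) and Krt6a from 7710 ± 1360 to 2420 ± 1160 CPM (log2 -1.67 ± 0.36, edgeR adjusted p = 0.0199). Cd14, a receptor of myeloid cells, fell from 41.7 ± 4.63 to 10.4 ± 4.26 CPM (log2 -2.01 ± 0.24, edgeR adjusted p = 0.00564). The PPARγ targets Fabp4, Angptl4 and Pdk4 had log2 1.22 ± 0.49, -0.30 ± 0.31 and 0.65 ± 0.68 (edgeR adjusted p = 0.128, 0.558 and 0.566).

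Of 17130 genes, 1599 changed, 803 higher and 796 lower. The count was 162 and 4464 without IMQ_Veh replicates 1 and 3, and 754 and 250 without IMQ_Troglitazone replicates 1 and 3. It was 708 after a correction for transcript length, 645 of them among the 1599, and a fit of the 6 libraries of these groups alone gave 0 by edgeR, with 3277 genes at an unadjusted p under 0.05; with all libraries DESeq2 gave 2558 and limma-voom 1972. Of 71 named genes past the threshold, 10 passed it in all 13 other fits run for named genes, which did not include the fit of these groups alone: Slc5a7, Fmo2, Flg2, Acod1, Cxcl3, Trem1, Ptgs2, Cd14, Cd36 and Hspa1a. Without IMQ_Veh replicates 1, 2 and 3, 59, 22 and 2 were lost, and without IMQ_Troglitazone replicates 1, 2 and 3, 35, 20 and 51. The lane field as a covariate ended 21 of the 71 calls and the length correction 27, among them S100a8, Srebf1, Il17a, Hbb-bs and Hba-a1; median lengths were 3370 bases for the higher genes and 1183 for the lower. The largest increases included those of Ibsp (log2 3.79 ± 0.85), Slc5a7 (3.60 ± 0.59), Galnt15 (3.03 ± 0.54), Fmo2 (2.82 ± 0.40), Flg2 and Hif3a (6.50-fold). The largest decreases included those of Acod1 (log2 -4.21 ± 0.78), Cxcl5 (-3.54 ± 0.79), Cxcl2 (-3.54 ± 0.71), Il1b, Cxcl3 (-3.46 ± 0.62) and Sprr2k (-3.41 ± 0.63). Without IMQ_Troglitazone replicate 3, Ibsp, Galnt15, Fmo2 and Hif3a were at log2 2.58, 2.24, 2.22 and 1.83, with Ibsp no longer past the threshold. Without IMQ_Troglitazone replicate 1, Acod1, Cxcl2, Il1b and Cxcl3 were at -6.08, -4.27, -4.06 and -4.55. Cxcl5 was at -4.27 without IMQ_Troglitazone replicate 2 and Slc5a7 at 5.05 without IMQ_Veh replicate 2.

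Several inflammatory lists were lower with troglitazone as well. Of 28 genes of the IL-23/IL-17 axis, 1 was higher and 7 lower, with 1 and 11 adjusted over the list alone (camera adjusted p = 6.7e-06, adjusted p = 0.355 with an estimated correlation). Il17a fell from 1.90 ± 1.43 to 0.234 ± 0.273 CPM (edgeR adjusted p = 0.0493), a call lost with the lane field, after the length or GC correction and without IMQ_Veh replicates 1 or 2 or IMQ_Troglitazone replicates 1 or 3, and Il17f and Il23a had edgeR adjusted p of 0.127 and 0.228. Of 15 antimicrobial genes, 5 were lower, with 9 adjusted over the list alone (camera adjusted p = 1.94e-07, adjusted p = 0.268 with an estimated correlation). Among them was Defb4 at log2 -2.34 ± 0.43, and S100a9 had an edgeR adjusted p of 0.0659. Of 29 wound keratin and envelope genes, 15 were lower, with 23 adjusted over the list alone (camera adjusted p = 7.77e-13, adjusted p = 0.288 with an estimated correlation). Krt16 had an edgeR adjusted p of 0.11. Of 29 suprabasal genes, 14 were higher, with 20 adjusted over the list alone (camera adjusted p = 6.94e-12, adjusted p = 0.288 with an estimated correlation). These included Lce1m and Hrnr at log2 1.75 ± 0.31 and 1.16 ± 0.25. Of 30 cell cycle genes, 9 were lower, with 15 adjusted over the list alone (camera adjusted p = 1.33e-09, adjusted p = 0.429 with an estimated correlation). They were led by Birc5 at log2 -0.92 ± 0.16. Of 17 neutrophil markers, 7 were lower, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 2.97e-08, adjusted p = 0.268 with an estimated correlation). Among them were Trem1 and Ptgs2 at log2 -2.52 ± 0.41 and -1.94 ± 0.35. Of 30 interferon-stimulated genes, Ly6a was lower at log2 -0.44 ± 0.10, also adjusted over the list alone (camera adjusted p = 0.00094, adjusted p = 0.604 with an estimated correlation), and without IMQ_Veh replicate 3 the list median was 0.01 and the camera adjusted p 0.793. Of 22 dendritic cell markers, Cd80 was lower at log2 -0.93 ± 0.21, also adjusted over the list alone (camera adjusted p = 0.00806, adjusted p = 0.592 with an estimated correlation), and it was not called without IMQ_Veh replicate 3 (0.237). Over the alternative fits camera adjusted p ranged from 1.51e-10 to 0.793 for interferon-stimulated genes and from 0.000117 to 0.237 for dendritic cells.

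Of 45 PPAR target genes, 6 were higher with troglitazone and 1 lower, with 8 and 2 adjusted over the list alone (camera adjusted p = 1.57e-05, adjusted p = 0.429 with an estimated correlation). Among them were Gpd1 and Plin4 at log2 1.91 ± 0.46 and 1.25 ± 0.28, with Gpd1 at 2.83 without IMQ_Veh replicate 3. Of 27 LXR target genes, 5 were higher and 1 lower, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.00291, adjusted p = 0.268 with an estimated correlation). Fasn and Srebf1 rose by log2 0.97 ± 0.19 and 0.57 ± 0.14. Of 27 fatty acid synthesis genes, 6 were higher, with 12 adjusted over the list alone (camera adjusted p = 3.18e-07, adjusted p = 0.243 with an estimated correlation). Of 22 sebaceous gland genes, 3 were higher, Awat2 among them at log2 1.46 ± 0.33, with 4 adjusted over the list alone (camera adjusted p = 6.7e-06, adjusted p = 0.344 with an estimated correlation). Of 18 adipocyte markers, Sult1a1 was higher at log2 1.67 ± 0.45 (1.04 and not past the threshold without IMQ_Troglitazone replicate 3), with 0 adjusted over the list alone by edgeR (camera adjusted p = 2.12e-05, adjusted p = 0.449 with an estimated correlation). Of 23 muscle markers, 0 passed edgeR's threshold over all genes or adjusted over the list alone, and 10 had an unadjusted p under 0.05. All 23 had a positive log2 value (camera adjusted p = 1.33e-07, adjusted p = 0.449 with an estimated correlation), and without IMQ_Veh replicate 3 all 23 were higher. Atp2a1 had log2 1.43 ± 0.45 (edgeR adjusted p = 0.0672), and muscle genes made up 0.911%, 0.764% and 1.117% of counts in the IMQ_Troglitazone libraries. Of 19 endothelial markers, Flt4 (log2 1.17 ± 0.24) and Lyve1 were higher, also adjusted over the list alone (camera adjusted p = 0.00816, adjusted p = 0.604 with an estimated correlation), and without IMQ_Veh replicate 2 the camera adjusted p was 0.509. Of 15 mast cell markers, 3 were higher, Tpsab1 among them at log2 1.56 ± 0.31, and Hdc lower at -0.83 ± 0.19, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.00273, adjusted p = 0.48 with an estimated correlation), and without IMQ_Veh replicate 2 the camera adjusted p was 0.0628. Of 7 erythrocyte genes, 4 were lower, Hbb-bt among them at log2 -1.68 ± 0.34, with 5 adjusted over the list alone (camera adjusted p = 6.94e-05, adjusted p = 0.355 with an estimated correlation). Over the alternative fits camera adjusted p ranged from 2.88e-06 to 0.509 for endothelium and from 2.29e-05 to 0.0628 for mast cells.

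The remaining lists were not called by camera against IMQ_Veh. Among monocyte markers Cd14 and Ccr2 fell by 2.01 ± 0.24 and 1.58 ± 0.28 while Gpnmb and Lyve1 rose by log2 1.45 ± 0.29 and 1.10 ± 0.21, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.596, and 0.0423 without IMQ_Veh replicate 3). Among type 2 genes Areg and Il33 fell by 1.53 ± 0.37 and 1.12 ± 0.28, as they did adjusted over the list alone (camera adjusted p = 0.382), and Il4ra had log2 -0.63 ± 0.29 (edgeR adjusted p = 0.178). Il4 and Il13 were at 0.0463 ± 0.0491 and 0.156 ± 0.163 CPM in IMQ_Troglitazone, too low to test. Clec7a and Arg1 fell by 2.35 ± 0.49 and 1.89 ± 0.53, with 1 higher and 3 lower macrophage genes of that list adjusted over the list alone (camera adjusted p = 0.982, direction down, median 0.14, mean -0.13). The only eosinophil and basophil marker past the threshold was Ms4a2, also adjusted over the list alone (camera adjusted p = 0.149). Among immediate early and heat shock genes Hspa1a rose by log2 0.62 ± 0.09 and Junb fell by 0.60 ± 0.14, with 3 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.251). In 6 further lists 0 genes passed the edgeR threshold over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 4 T cell markers, 0 B cell markers, 5 cholesterol synthesis genes, 4 cartilage markers, 1 hair keratin and 2 fibroblast genes. Camera gave adjusted p of 0.154 for T cell markers, 0.526 for B cell markers, 0.282 for cholesterol synthesis, 0.154 for cartilage, 0.699 for hair keratins and 0.845 for fibroblast genes. Abundant members were Thy1 and Trbc2 (log2 -0.09 ± 0.19 and -0.59 ± 0.17), Blnk and Ighm (-0.01 ± 0.13 and -0.37 ± 0.40), Hmgcs1 (0.16 ± 0.15), Cytl1 (1.23 ± 0.37), Krt75 (-0.78 ± 0.25), and Col3a1 and Dcn (-1.36 ± 0.58 and 0.62 ± 0.23). Camera called cholesterol synthesis without IMQ_Veh replicate 1 (adjusted p = 0.0124), cartilage without IMQ_Veh replicate 3 (5.44e-07), and fibroblast genes without IMQ_Veh replicate 2 (0.00686, median -0.38) or 3 (0.00137, median 0.46). Nr1h2, Nr1h3, Pparg, Abca1 and Abcg1 had edgeR adjusted p of 0.0856, 0.206, 0.0593, 0.227 and 0.936. Camera adjusted p over the alternative fits ranged from 0.0423 to 0.734 for monocytes, 0.0124 to 0.934 for cholesterol synthesis, 5.44e-07 to 0.616 for cartilage and 0.00137 to 0.951 for fibroblasts.

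**Figure D2:**
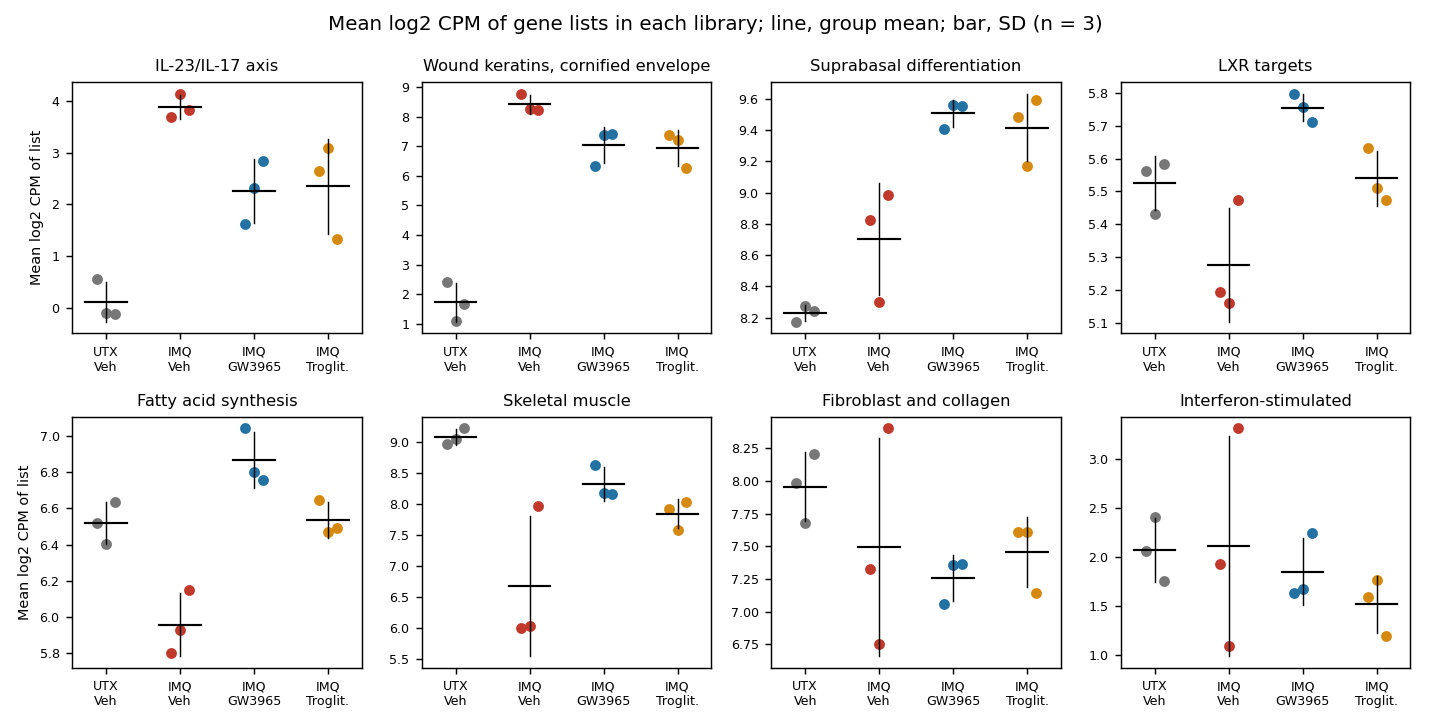
Mean log2 CPM of 8 gene lists in each library, with points for libraries, lines for group means and bars for the SD (n = 3). IMQ_Veh replicate 3 lies above the other IMQ_Veh libraries in the muscle, fibroblast and interferon-stimulated lists.

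Drug changes were set against those in IMQ_Veh. Il1b, S100a8 and Krt6a, higher in IMQ_Veh than UTX_Veh, were lower with either drug, and Flg2 and Srebf1, lower in IMQ_Veh, were higher with either. With GW3965, 389 and 495 genes opposed the rise or fall in IMQ_Veh, against 162.8 and 183.8 for independent lists, and 36 and 18 followed it. With troglitazone 761 and 647 opposed it, against 262.3 and 232.1, and 37 and 3 followed it. Sharing IMQ_Veh alone could raise the opposed counts. They were not repeated after length correction. Across genes, which are not independent replicates, the fold changes had r = -0.631 and -0.686 for GW3965 and troglitazone, where 40 simulations of unchanged groups sharing the IMQ_Veh libraries gave means of -0.149 and -0.155. The covariances were -0.472 and -0.49 (simulated means -0.081 and -0.083). They were -0.479 and -0.458 after the length correction and -0.749 and -0.761 without IMQ_Veh replicate 3.

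**Figure D3:**
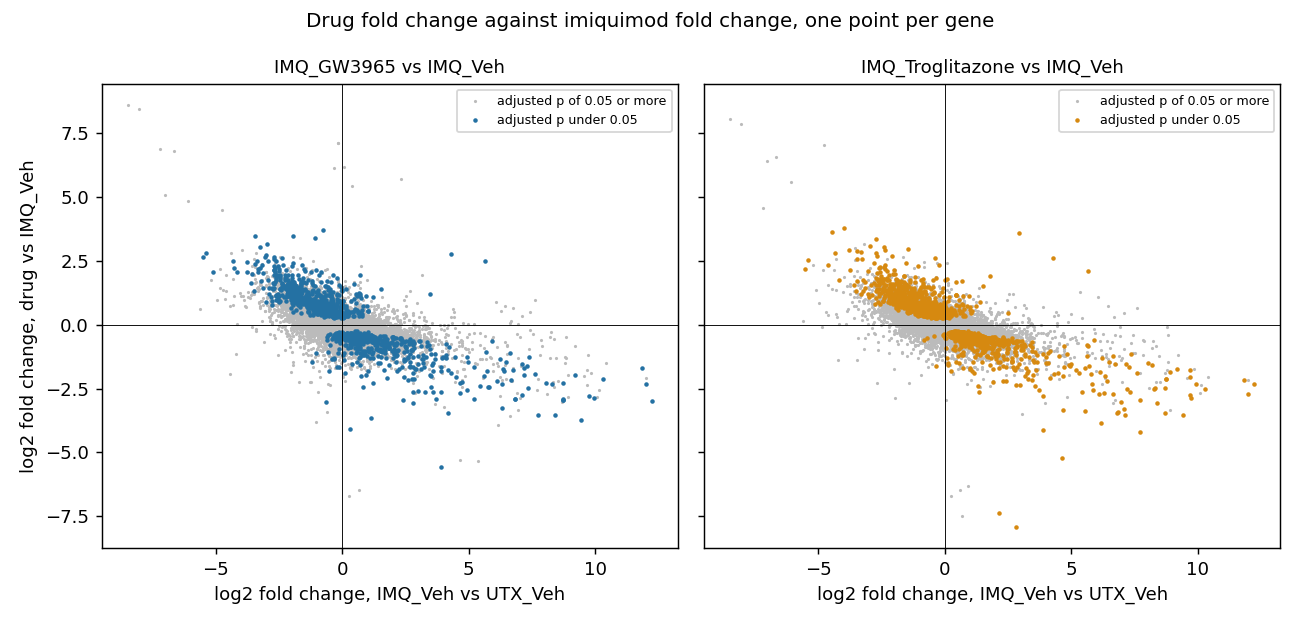
Log2 fold change of each drug group against IMQ_Veh, plotted over the log2 fold change of IMQ_Veh against UTX_Veh, with 1 point per gene and colour for an edgeR adjusted p under 0.05. Both axes share the IMQ_Veh libraries, which alone tilts the cloud downward; r was -0.631 for GW3965 and -0.686 for troglitazone.

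The drugs shared many of their changes. Il1b, Acod1, Cxcl3 and Cxcl5 were lower and Flg2, Fmo2 and Galnt15 higher with each. In all, 341 genes were higher and 211 lower with both, where independent lists would share 29.8 and 23, and 1 gene changed in opposite directions. Across genes r was 0.753, against a simulated mean of 0.498 from the shared IMQ_Veh libraries, and the covariance 0.251, against 0.085 (0.452 without IMQ_Veh replicate 3). With each drug set against different IMQ_Veh libraries, 1 for one drug and 2 for the other, the 6 divisions gave r from 0.243 to 0.592 and covariances from 0.088 to 0.207. The 3 control libraries could not be split into parts of at least 2, so part of the excess may come from the shared controls.

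The direct comparison of IMQ_GW3965 with IMQ_Troglitazone tested where the drugs differed. Scd3 was at 74.3 ± 23.3 CPM with GW3965 and 7.46 ± 1.51 CPM with troglitazone (log2 3.31 ± 0.65, edgeR adjusted p = 0.0362). Srebf1 was at 308 ± 41.4 and 194 ± 23.5 CPM (log2 0.66 ± 0.14, edgeR adjusted p = 0.0437), and Apoe at 2000 ± 52.7 and 1420 ± 156 CPM (log2 0.50 ± 0.11, edgeR adjusted p = 0.0492). Elovl5 (ENSMUSG00000032349, chromosome 9, 77917364 to 77984519), a fatty acid elongase, was at 81.7 ± 9.63 and 45.7 ± 1.98 CPM (log2 0.84 ± 0.10, edgeR adjusted p = 0.0234). Slc5a7 (ENSMUSG00000023945, chromosome 17, 54273590 to 54299034), a choline transporter, was at 0.996 ± 0.549 and 7.01 ± 2.45 CPM (log2 -2.76 ± 0.56, edgeR adjusted p = 0.0388). Cd36, S100a8, S100a9, Krt6a, Krt16 and Il17a had edgeR adjusted p between 0.683 and 0.982.

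Of 17130 genes, 319 differed, 185 higher and 134 lower with GW3965, and these followed transcript length: median lengths were 683 bases for the higher genes, 5752 for the lower ones and 2399 for all. After a correction of each library for length, 1 gene passed the edgeR threshold, Elovl5 (log2 0.86 ± 0.10, edgeR adjusted p = 0.0319); the median absolute log2 of the 319 genes went from 0.489 to 0.205 with median SE of 0.092 and 0.09. The count was 51 and 73 without IMQ_GW3965 replicate 2 and IMQ_Troglitazone replicate 1, and 0 by edgeR without IMQ_GW3965 replicates 1 and 3 or IMQ_Troglitazone replicates 2 and 3, with 2429, 1986, 2038 and 2611 genes at an unadjusted p under 0.05. With all libraries DESeq2 gave 939 and limma-voom 386. The balance turned to 444 higher and 495 lower by DESeq2, 134 and 138 with RLE scaling, 65 and 75 with no filter, 172 and 201 after the GC correction, and 10 and 41 or 34 and 39 without IMQ_GW3965 replicate 2 or IMQ_Troglitazone replicate 1. Of 21 named genes past the threshold, 0 passed it in each of the 13 other fits. Other differences upward included Hbb-bs (log2 1.39 ± 0.30) and Fam25c (0.70 ± 0.11), and downward Zfp993 (-1.46 ± 0.31), Lrp1 (-0.93 ± 0.17) and Spen (-0.88 ± 0.16).

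**Figure D4:**
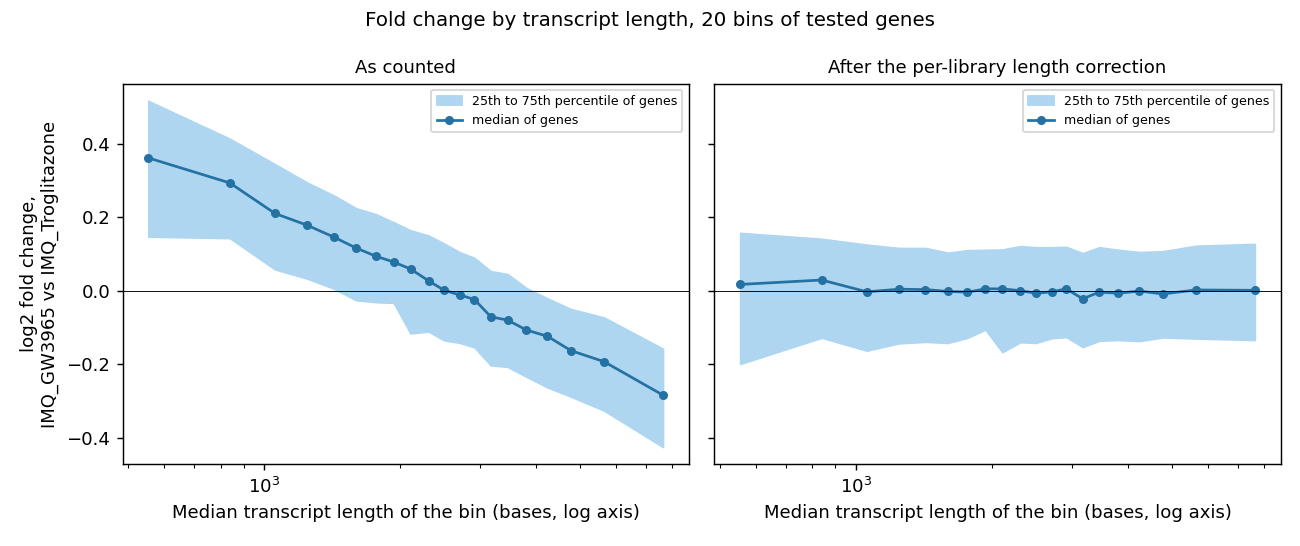
Median log2 fold change between IMQ_GW3965 and IMQ_Troglitazone in 20 bins of transcript length (log axis), with shading from the 25th to the 75th percentile of genes, as counted and after the length correction. As counted, bin medians run from 0.36 at 554 bases to -0.28 at 7626 bases.

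Of the lipid lists, camera called those of LXR targets and fatty acid synthesis between the drugs. Of 27 LXR target genes, Srebf1, Apoc1 (log2 0.64 ± 0.13) and Apoe were higher with GW3965, with 4 adjusted over the list alone (camera adjusted p = 0.00236, adjusted p = 0.304 with an estimated correlation). After length correction these were 1.01e-07 and 0.026. Of 27 fatty acid synthesis genes, Scd3, Elovl5 and Srebf1 were higher, with 4 adjusted over the list alone (camera adjusted p = 0.000928, adjusted p = 0.304 with an estimated correlation; 1.26e-10 and 0.0269 after length correction). Of 7 erythrocyte genes, Hbb-bs was higher, and 7 adjusted over the list alone (camera adjusted p = 1.02e-09, adjusted p = 0.304 with an estimated correlation). Of 23 muscle markers, 0 passed the edgeR threshold over all genes or adjusted over the list alone and 0 had an unadjusted p under 0.05, with Myh1 and Atp2a1 at log2 -0.04 ± 0.36 and 0.24 ± 0.44 (camera adjusted p = 0.00954, adjusted p = 0.962 with an estimated correlation), and the camera adjusted p was 0.127 and 0.0854 without IMQ_GW3965 replicate 1 and IMQ_Troglitazone replicate 2. Acaa2 (log2 0.37 ± 0.08) was the 1 PPAR target gene that differed, also adjusted over the list alone (camera adjusted p = 0.548, direction up, median 0.06, mean -0.03, and 0.0273 without IMQ_Troglitazone replicate 3). Of 26 cholesterol synthesis genes, 1 was higher, with 3 adjusted over the list alone (camera adjusted p = 0.0848, and 0.00405 without IMQ_Troglitazone replicate 1). Scd3 was the 1 sebaceous gland gene, also adjusted over the list alone (camera adjusted p = 0.0848, and 0.0218 and 0.0135 without IMQ_GW3965 replicate 2 and IMQ_Troglitazone replicate 3). Across the alternative fits camera adjusted p ranged from 1.01e-07 to 0.0135 for LXR targets, 1.26e-10 to 0.0195 for fatty acid synthesis, 1.43e-15 to 0.127 for muscle, 0.0273 to 0.677 for PPAR targets, 0.00291 to 0.291 for cholesterol synthesis and 0.0135 to 0.266 for sebaceous genes.

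In the other 21 lists 0 genes passed the edgeR threshold between the drugs, over all genes or adjusted over the list alone, and none was called by camera. At an unadjusted p under 0.05 they held 0 to 3 genes each, apart from 7 of the suprabasal list. Camera adjusted p was 0.674 for the IL-23/IL-17 axis, 0.846 for antimicrobial genes (median 0.06, mean -0.02), 0.548 for wound keratins, 0.579 for suprabasal genes, 0.846 for the cell cycle, 0.0848 for interferon-stimulated genes and 0.917 for neutrophils. It was 0.333 for monocytes, 0.846 for T cells, 0.917 for type 2 genes, 0.196 for alternatively activated macrophages, 0.379 for eosinophils, 0.119 for mast cells, 0.602 for dendritic cells and 0.352 for B cells. For adipocytes, cartilage, hair keratins (median 0.01, mean -0.52), fibroblasts, endothelium and immediate early genes it was 0.654, 0.588, 0.891, 0.196, 0.296 and 0.405. Without IMQ_GW3965 replicate 1, camera called wound keratins (adjusted p = 0.00678) and interferon-stimulated genes (0.0195), the latter also without IMQ_GW3965 replicate 2 (0.0195) or IMQ_Troglitazone replicate 2 (0.00933), and without IMQ_Troglitazone replicate 3 it called the IL-23/IL-17 axis (0.0305) and fibroblast genes (0.0176). Among abundant members, Fn1, Tchh, Mrc1, Gata2, Trbc2, Asprv1, Ighm and Cytl1 had log2 -0.80, -0.59, -0.48, -0.39, 0.36, 0.39, 0.41 and 0.71 (edgeR adjusted p between 0.305 and 0.671). Il4ra, Pparg, Abca1, Abcg1, Nr1h2, Nr1h3, Fabp4, Angptl4, Pdk4, Il17f and Il23a had edgeR adjusted p between 0.211 and 0.975. Camera adjusted p across the alternative fits ranged from 0.00678 to 0.992 for wound keratins, 0.00933 to 0.498 for interferon-stimulated genes, 0.0305 to 0.995 for the IL-23/IL-17 axis and 0.0061 to 0.445 for fibroblasts.

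Each drug group was also compared with UTX_Veh, which shares no IMQ_Veh library. Wound keratins and envelope precursors, 29 of 29, and cell cycle genes, 30 of 30, were higher than in UTX_Veh with either drug, also adjusted over the list alone. For wound keratins the camera adjusted p was 9.7e-31 with GW3965 and 3.52e-36 with troglitazone, and for the cell cycle 9.6e-30 and 2.87e-36. With an estimated correlation both lists had adjusted p = 0.209 and 0.16. In the IL-23/IL-17 axis 16 of 28 genes were higher with GW3965 and 22 with troglitazone (18 and 24 adjusted over the list alone), and 1 lower in each. Camera adjusted p was 5.04e-06 and 1.39e-07, and 0.477 and 0.38 with an estimated correlation. LXR target genes were 9 higher and 3 lower with GW3965 (8 and 1 adjusted over the list alone, camera adjusted p = 0.56) and 5 higher and 8 lower with troglitazone (the same adjusted over the list alone, camera adjusted p = 0.643). In all, 8606 genes differed from UTX_Veh with GW3965, 4924 higher and 3682 lower, and 7768 with troglitazone, 4545 higher and 3223 lower; with upper-quartile scaling the share higher went from 57.2% to 47.2% and from 58.5% to 44.7%.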

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

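Of the tests in this part, those of transcript length and GC content, with the list tests after the length correction, were chosen only after the result was seen.

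GW3965 and troglitazone differed in 319 genes, and these followed transcript length, with rho = -0.52 between length and log2 fold change across genes, which are not independent replicates. After a per-library length correction 1 gene remained past the edgeR threshold, so a length trend of the libraries, such as RNA integrity or fragment selection could give, may explain most of the count. After a correction for GC content 373 genes were called, 283 of the 319 among them, so a GC trend does not explain it. The LXR target list was still higher with GW3965 after the length correction (camera adjusted p = 1.01e-07, adjusted p = 0.026 with an estimated correlation). This does not bear on the source of the trend, which stays open. A real change of long or short transcripts would be removed by the same correction.

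The lists that camera called between the drugs, compared directly, were LXR target genes (median log2 0.204), fatty acid synthesis (0.092), muscle markers (0.632) and erythrocyte genes (1.212). In this order they had adjusted p = 0.304, 0.304, 0.962 and 0.304 with an estimated correlation, and fry gave adjusted p of 0.0754, 0.0754, 0.923 and 0.0754, so neither called any of them. Of the LXR target and of the fatty acid synthesis genes, 9 each are also in another list, so these results are not independent. Camera also called muscle and erythrocyte genes after the length correction (median log2 0.471 and 0.904, adjusted p = 0.935 and 0.141 with an estimated correlation), and what set them apart stays open. The muscle call ended without IMQ_GW3965 replicate 1 (camera adjusted p = 0.127) or IMQ_Troglitazone replicate 2 (0.0854).

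Splits of the 6 libraries of each comparison were counted as well. Only 1 of 10 splits, the real one, gave as many genes changed in each of the 6 comparisons: 10595, 1130, 1599, 319, 8606 and 7768. The highest other split gave 0 genes by edgeR in each, except 1 gene between the drugs, but 10 splits are too few for a share under 0.05.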

How the results depend on the processing

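All tests of this part were fixed before the data were examined, except the fits without IMQ_Veh replicate 3 and IMQ_GW3965 replicate 3 together (below, both doubted libraries), those without the feature ENSMUSG00000119584 and Lars2, and the corrections for transcript length and GC content, which were chosen only after the result was seen. Groups of 3 libraries limit the drug comparisons: with simulated counts for GW3965 against IMQ_Veh, 9 of 67 genes changed 1.5-fold were found and 40 of 67 changed 2-fold. Counts under alternatives not named below stayed within 1.5 times. For each moved value below the cause was not tested.

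Counts of genes changed against UTX_Veh stayed within 1.5 times in each alternative. IMQ_Veh had 10595 (9340 to 11282 with 1 library left out), GW3965 8606 (6845 to 8309) and troglitazone 7768 (5808 to 7532). Length correction called 9302, 6639 and 7109 of these again. For GW3965 against IMQ_Veh (1130) the lane field as a covariate gave 549, leaving out both doubted libraries 3040, a fit of only these groups 103 and DESeq2 2177, and leaving out 1 library gave 105 to 3644. For troglitazone against IMQ_Veh (1599) the lane field gave 1009, both doubted libraries out 4165, the length correction 708, DESeq2 2558 and a fit of only these groups 0 by edgeR, with 3277 genes at an unadjusted p under 0.05, and leaving out 1 library gave 162 to 4464. Between the drugs (319) no filter on low counts gave 140, the length correction 1, a fit of only these groups 9 and DESeq2 939. Both doubted libraries out gave 0 by edgeR, with 2623 genes at an unadjusted p under 0.05, and leaving out 1 library gave 0 to 73. Without a filter the share of higher genes for troglitazone against IMQ_Veh went from 50.2% to 61.5%. Genes higher became fewer than genes lower for IMQ_Veh against UTX_Veh with both doubted libraries out (5486 of 11165), for GW3965 against IMQ_Veh after the GC correction (646 of 1299), and for troglitazone against IMQ_Veh with upper-quartile scaling (782 of 1640), a filter of 1 CPM in 3 libraries (840 of 1687), the lane field (503 of 1009) and the GC correction (826 of 1690). Length correction reversed the sign of 15 IMQ_Veh and 16 GW3965 calls against UTX_Veh.

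Whether the replicate numbers pair libraries was not settled. The best correlated library of another group had the same number in 13 of 36 cases. A correlation above 0.1 was seen in 4 of 18 pairs with the same number against 2 of 36 others. With the number as a replicate block the counts were 10723 for IMQ_Veh, 8723 for GW3965 and 7912 for troglitazone against UTX_Veh, 1426 and 1716 for GW3965 and troglitazone against IMQ_Veh, and 131 between the drugs (61 higher and 70 lower). A replicate block with the lane field gave 991 for troglitazone against IMQ_Veh and 26 between the drugs (4 higher and 22 lower). The replicate block added a camera call of mast cell genes for GW3965 against IMQ_Veh (median log2 0.52) and changed no other list call.

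Covariances kept their sign. Without 1 IMQ_Veh library the shared effect of the drugs (0.251) was 0.249 to 0.452, that of GW3965 with the imiquimod response (-0.472) -0.749 to -0.436 and that of troglitazone (-0.49) -0.761 to -0.456. With both doubted libraries out they were 0.471, -0.81 and -0.76.

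With an estimated correlation camera no longer called 45 of its list calls, given here with the median log2. These were for IMQ_Veh against UTX_Veh IL-17 axis (5.21), antimicrobial (5.97), wound keratins (7.83), cell cycle (2.50), neutrophil (4.54), monocyte (1.22), cholesterol (0.79), fatty acid (-0.75), sebaceous (-0.79), adipocyte (-1.12), muscle (-1.92) and cartilage (-1.71). With members at 0 counts set to their bound, the medians of the IL-17 axis and antimicrobial lists were 5.11 and 5.81. For GW3965 against IMQ_Veh they were IL-17 axis (-1.52), antimicrobial (-1.53), wound keratins (-1.31), suprabasal (0.57), cell cycle (-0.47), neutrophil (-1.33), dendritic (-0.33), PPAR (0.52), cholesterol (0.13), sebaceous (0.94), adipocyte (0.92) and muscle (1.27). For troglitazone against IMQ_Veh they were IL-17 axis (-1.14), antimicrobial (-1.71), wound keratins (-1.55), suprabasal (0.62), cell cycle (-0.39), interferon (-1.01), neutrophil (-1.18), mast cell (0.67), dendritic (-0.43), LXR (0.27), PPAR (0.33), fatty acid (0.40), sebaceous (0.67), adipocyte (0.92), muscle (0.85), endothelial (0.25) and erythrocyte (-1.06). Between the drugs they were LXR (0.20), fatty acid (0.092), muscle (0.63) and erythrocyte (1.21). Fry did not call 17 of these lists: cell cycle, dendritic, cholesterol and adipocyte for GW3965 against IMQ_Veh, cell cycle, interferon, mast cell, dendritic, PPAR, adipocyte, muscle, endothelial and erythrocyte for troglitazone against IMQ_Veh, and LXR, fatty acid, muscle and erythrocyte between the drugs. It added suprabasal (0.58), T cell (-0.58), type 2 (0.40), B cell (1.36), LXR (-0.33), immediate early (0.22) and erythrocyte (1.56) for IMQ_Veh against UTX_Veh.

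Leaving out both doubted libraries ended the camera calls of monocyte (0.85) and sebaceous (-0.71) for IMQ_Veh against UTX_Veh, dendritic (-0.27) and cholesterol (0.018) for GW3965 against IMQ_Veh and interferon (0.029) and dendritic (-0.24) for troglitazone against IMQ_Veh. It added fibroblast (-0.98) for IMQ_Veh against UTX_Veh, mast cell (0.89), cartilage (0.58) and endothelial (0.76) for GW3965 against IMQ_Veh, cartilage (0.61) and fibroblast (0.47) for troglitazone against IMQ_Veh, and IL-17 axis (-0.37), monocyte (-0.15), alternative macrophage (-0.36), mast cell (-0.21) and fibroblast (-0.30) between the drugs. The length correction ended fatty acid (-0.65) and added T cell (-0.77) for IMQ_Veh against UTX_Veh, and added interferon (0.26), mast cell (-0.32) and cholesterol (0.082) between the drugs. The lane field ended dendritic (-0.26) and added endothelial (0.32) for GW3965 against IMQ_Veh. RLE scaling, the GC correction and removal of ENSMUSG00000119584 and Lars2 changed none of 112 list calls.

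With 1 library left out, 630 list results kept their side of the threshold, 30 gained a call and 12 lost it. Medians of the lists concerned ranged as follows: for IMQ_Veh against UTX_Veh suprabasal (0.49 to 0.66), monocyte (0.89 to 1.49), T cell (-0.71 to -0.41), sebaceous (-1.11 to -0.67), fibroblast (-0.94 to -0.006) and erythrocyte (1.299 to 1.81). For GW3965 against IMQ_Veh they ranged for interferon (-1.05 to 0.37), monocyte (-0.29 to 0.28), T cell (-0.30 to -0.061), alternative macrophage (-0.40 to 0.12), mast cell (0.10 to 0.82), dendritic (-0.48 to -0.15), cholesterol (0.053 to 0.26), cartilage (-0.36 to 0.64), fibroblast (-0.54 to 0.17) and endothelial (-0.13 to 0.77). For troglitazone against IMQ_Veh they ranged for interferon (-1.50 to 0.013), monocyte (-0.16 to 0.41), mast cell (0.38 to 1.15), dendritic (-0.59 to -0.25), cholesterol (-0.046 to 0.18), cartilage (-0.23 to 0.59), fibroblast (-0.38 to 0.46) and endothelial (-0.068 to 0.84). Between the drugs they ranged for IL-17 axis (-0.47 to 0.22), wound keratins (-0.14 to 0.31), interferon (0.072 to 0.47), PPAR (-0.001 to 0.16), cholesterol (0.052 to 0.15), sebaceous (0.15 to 0.31), muscle (0.42 to 0.70) and fibroblast (-0.33 to -0.080). Of results for named genes, 1793 were the same with 1 library left out, 537 lost the call and 28 gained it.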

Other observations

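The tests in this part, apart from the simulation of shared libraries and the adipocyte list, were chosen only after the result was seen.

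Drug fold changes ran opposite to the imiquimod fold changes, and shared IMQ_Veh libraries could give such a pattern. In a simulation, whose prediction was written beforehand, the observed covariances lay below all simulated ones, at -0.39 for GW3965 and -0.407 for troglitazone relative to the simulated means. Since simulated bounds exclude nothing, it was replaced after this was seen by differences with disjoint IMQ_Veh libraries on each side. Of the 6 ways to divide them, the highest covariance was -0.191 for GW3965 and -0.207 for troglitazone, which argues against shared libraries as the only source. How far the drugs reversed the response, and how far the groups differed in severity for other reasons, stays open.

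More deep ear tissue with the drugs could also lower epidermal and inflammatory genes. Suprabasal medians were 0.571 and 0.616 with GW3965 and troglitazone, arguing against dilution of the whole epidermis. The muscle list has 23 tested genes, 0 in another list and 23 above 1 CPM in UTX_Veh, where Atp2a1 and Myh1 were at 3240 ± 299 and 2980 ± 262 CPM. The fibroblast list has 21, 3 and 21, with Sparc and Dcn at 1780 ± 246 and 1510 ± 251 CPM. Muscle minus fibroblast scores changed by log2 1.89 with GW3965 and 1.21 with troglitazone (pooled SD 0.45 and 0.46), and by 2.08 and 1.41 without IMQ_Veh replicate 3, so these 2 lists did not rise alike. Adipocyte medians were 0.917 and 0.922 (adjusted p = 0.363 and 0.449 with an estimated correlation, fry 0.065 and 0.1), though only 2 and 1 of 18 genes passed the edgeR threshold. A larger share of some deeper tissues may still be present.

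IMQ_Veh replicate 3 exceeded the mean of the other IMQ_Veh libraries by at least log2 1.17 in the muscle, cartilage, adipocyte, endothelial and fibroblast lists, each by more than the gap between the others, which a larger share of deeper tissue could give. Its interferon-stimulated score was higher by 1.80 as well (gap 0.84), which that explanation does not cover. The cartilage, adipocyte and endothelial lists had 18, 18 and 19 tested genes, all above 1 CPM in UTX_Veh, with 0, 7 and 1 in another list. Cytl1, Car3 and Pecam1 were at 1510 ± 273, 519 ± 105 and 57.9 ± 10.6 CPM there.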
